A study of Mus musculus with 55 samples.

How the data were processed

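Liver messenger RNA of 55 male mice was measured by poly(A)-selected, strand-specific sequencing. The 2 strains and 3 vectors made 6 groups, with 10 WT control, 10 WT sh-Gls2, 9 WT sh-Glud1, 8 OTC control, 10 OTC sh-Gls2 and 8 OTC sh-Glud1 libraries. The mouse numbers do not pair mice across groups, and the labels name no sequencing batch. For 1 library the mouse number in the table of values differs from the number in the sample titles; its strain and vector were taken from the table, and it is called the unnumbered OTC control here.

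The authors deposited read counts per gene symbol for each library, and the counts were whole numbers that had not been normalized. The authors also deposited TPM values (transcript abundances scaled to a fixed total), whose columns each summed to between 999999 and 1000001. Per the labels, the authors' steps included CASAVA 1.8.2, FastQC and the genome build GRCm38. The aligner, the counting program and the annotation were not given in the sources used here. Of the 24475 gene symbols in the count table, 4775 had no count in any library. Gene positions were looked up by symbol in GENCODE M21 on GRCm38, which held 23384 of the symbols.

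Total counts per library lay between 14489866 and 22781052, with a median of 18683991. The libraries were amplified by PCR and carried no molecular identifiers, so reads were not independent molecules and the counts' own error is a lower limit of the error. Standard deviations (SD) between mice therefore serve as the measure of error for each group. Library pairs within each group were checked for duplicates, and the smallest ratio of chi-square to its degrees of freedom over 227 pairs was 11.1. This is far above the value near 1 that repeated sequencing of the same library would give. Pairs of libraries from different groups were not checked.

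Tests used edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for gene lists and for TPM and DESeq2 1.42.0 as an alternative. Genes passed edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 13311 genes. Counts were scaled by TMM factors, which lay between 0.924 and 1.12. A quasi-likelihood F test was fitted over all 55 libraries with 1 term for each of the 6 groups. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the 13311 genes, and all tests were two-sided. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Levels are given as TMM-normalized CPM, the count of a gene scaled to the effective total of its library.

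Comparisons were OTC with WT under the control vector, each hairpin with the control vector within each strain, the difference between strains in each hairpin's effect, and the hairpins with each other within each strain. Before the data were examined, 35 gene lists of liver pathways and liver cell types were written down, together with the comparisons, the rule for naming genes and the alternatives. A list needed 4 tested genes, which 33 lists had. Lists were tested with fry of limma, adjusted over the 33 lists of a comparison. The fry test asks whether the genes of a list move in 1 direction on balance and does not compare them with other genes. For each called list, camera with a correlation estimated from the data, which does compare with other genes, is given beside fry.

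The genes named were Otc, Gls2 and Glud1, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 1 log2 CPM and a name other than a predicted one, and up to 4 genes with the smallest adjusted p in each called list. Values are given for part of the genes that the rule selected, and that part was picked after the values were seen. Every called gene with such a name was named where fewer than 16 were called. For differences between strains and between hairpins the rule took the 5 genes with the smallest adjusted p in each direction. Members of gene families with near-identical sequences share reads, so their single-gene values are uncertain.

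Alternatives were DESeq2 size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in at least 8 libraries, the DESeq2 Wald test, a fit of the compared groups only, the mouse number as a covariate, and limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean of at least 1 TPM. Each library of the compared groups was also left out in turn. Added after the data were seen were fits without the WT control library of mouse 13, without the OTC control libraries of mice 03 and 67, and without these 3 libraries, and the single-library omissions for each named gene. The pipeline was tested on simulated counts with the means, dispersions and library sizes of the real data, in which 200 genes were changed. For the comparison of sh-Glud1 with control in WT, it recovered 71.6% of genes changed 1.5-fold and 86.6% of genes changed 2-fold, with 6 false calls of 177. For sh-Gls2 with control in WT these shares were 73.1% and 85.1%, with 14 false calls of 186 (7.53%, above the 5% of the threshold), and for OTC with WT they were 70.1% and 92.5%, with 4 of 178. The unnumbered OTC control was left out of the fit with the mouse number, which held 54 libraries.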

Results

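The series asks whether lowering enzymes that release ammonia from glutamine and glutamate changes the disease of mice that cannot clear ammonia through the urea cycle. WT mice were the hybrid B6EiC3SnF1/J, and OTC mice were of the stock B6EiC3Sn a/A-Otcspf-ash/J, which carries a variant of the X-linked gene Otc (ornithine transcarbamylase, the urea cycle enzyme that makes citrulline). All mice were male and 4 months old when they received an adeno-associated virus, a vector that carries DNA into liver cells, by vein. The virus encoded a scrambled control hairpin, a short hairpin RNA against Gls2 (sh-Gls2) or a short hairpin RNA against Glud1 (sh-Glud1). Mice ate a diet with 40% protein from week 2, and livers were taken at week 5. Total counts per library lay between 16023185 and 22781052 in WT control, 14489866 and 22001267 in WT sh-Gls2, 15321137 and 21052417 in WT sh-Glud1. They lay between 15629514 and 20717610 in OTC control, 15033685 and 21017325 in OTC sh-Gls2, and 15720335 and 22672786 in OTC sh-Glud1. Each library held between 15408 and 16189 genes with a count. The first 2 principal components of the log2 CPM held 26.3% and 17.7% of the variance.

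Otc, Gls2 and Glud1 each had fewer reads in the groups in which they were altered or targeted. Otc (ENSMUSG00000031173.13, GRCm38 chromosome X, 10252305 to 10321024) was at 522 ± 38.5 CPM (SD, n = 10) in WT control and 61.2 ± 11.7 CPM (SD, n = 8) in OTC control. Gls2, the glutaminase of the liver (ENSMUSG00000044005.13, chromosome 10, 128194460 to 128210000), was at 441 ± 67.2 CPM (SD, n = 10) in WT control and 204 ± 30.01 CPM (SD, n = 10) in WT sh-Gls2. In OTC livers Gls2 was at 439 ± 84.4 CPM (SD, n = 8) under control and 198 ± 23.9 CPM (SD, n = 10) under sh-Gls2. Glud1, glutamate dehydrogenase (ENSMUSG00000021794.16, chromosome 14, 34310727 to 34345265), was at 1035 ± 103 CPM (SD, n = 10) in WT control and 386 ± 123 CPM (SD, n = 9) in WT sh-Glud1. In OTC livers Glud1 was at 1068 ± 121 CPM (SD, n = 8) under control and 444 ± 105 CPM (SD, n = 8) under sh-Glud1. The log2 fold change of Gls2 was −1.11 ± 0.10 (SE) in WT (edgeR adjusted p = 3.51e-13) and −1.15 ± 0.10 in OTC (edgeR adjusted p = 6.85e-13). The log2 fold change of Glud1 was −1.42 ± 0.12 in WT (edgeR adjusted p = 3.96e-12) and −1.27 ± 0.13 in OTC (edgeR adjusted p = 3.7e-09). In each of these 4 comparisons, every library with the hairpin was below every control library. Neither knockdown differed between strains in edgeR (Gls2 adjusted p = 0.957, Glud1 adjusted p = 0.999). Gls2 was at 98.4% and 98.8% of control under sh-Glud1 in WT and OTC, and Glud1 was at 95.8% and 98.8% of control under sh-Gls2, with no call in edgeR.

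**Figure D1:**
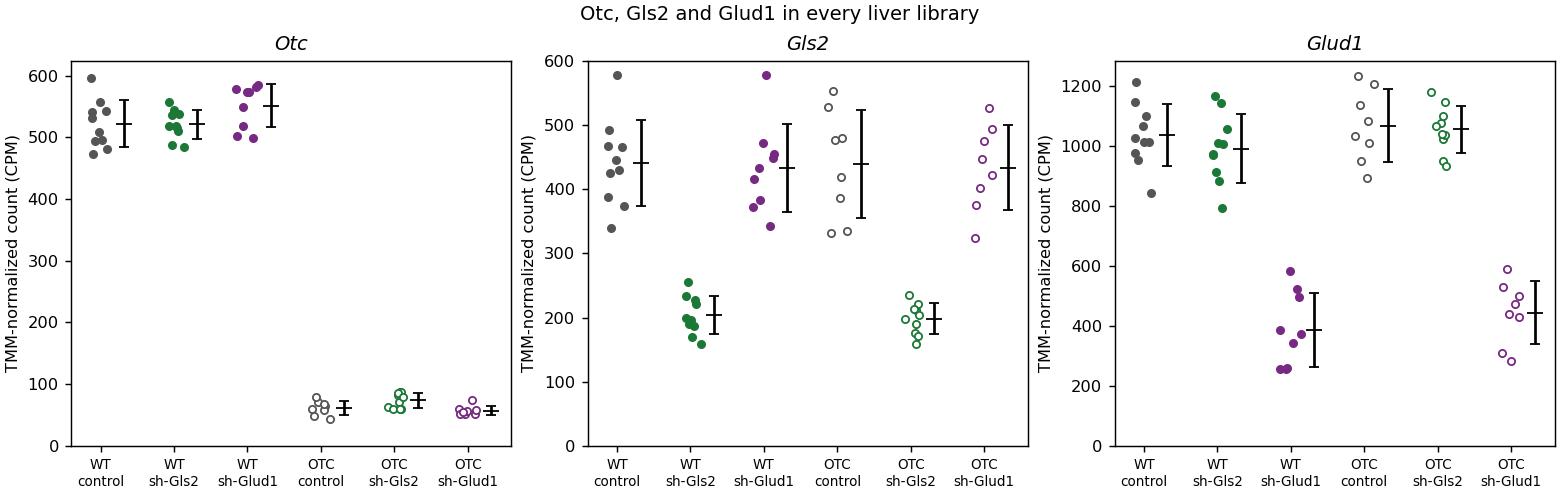
TMM-normalized counts (CPM) of Otc, Gls2 and Glud1 in each of the 55 libraries by group, with the mean and SD of the group beside the points. Gls2 was at 46.3% of control under sh-Gls2 in WT and 45.1% in OTC, Glud1 was at 37.3% and 41.6% of control under sh-Glud1, and Otc was at 11.7% of WT in OTC control livers.

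Otc rose under sh-Gls2 in OTC livers, from 61.2 to 73.5 CPM (log2 fold change 0.27 ± 0.08, edgeR adjusted p = 0.00874), with overlapping ranges of 43.02 to 79.1 and 59.5 to 87.2 CPM. The call of Otc was lost in a fit of the compared groups only (adjusted p = 0.0706) and without OTC control mice 03 and 67 (adjusted p = 0.075). The effect on Otc was not shown to differ from that in WT (difference 0.27 ± 0.11, edgeR adjusted p = 0.356).

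The comparison of OTC with WT under the control vector asks how the liver of the OTC stock differed on the high-protein diet. Most of the tested genes that male livers express more than female livers were lower in OTC. Glutamine synthetase and other genes of hepatocytes around the central vein were lower, and several genes of hepatocytes around the portal vein were higher. Of the tested genes, 26 of 40 interferon-stimulated genes and 12 of 19 targets of the tumour suppressor p53 were higher, and 15 of 16 chaperones and stress genes of the endoplasmic reticulum were lower. No list was called by camera with an estimated correlation, which compares a list with other genes. For the lists that fry called, the adjusted p of camera was from 0.596 to 0.769. The 2 strains differ in their background as well as in Otc, so these differences cannot be assigned to the Otc variant. In edgeR, 4830 of 13311 genes were called, 2650 higher and 2180 lower in OTC, of which 303 were at least 2-fold higher and 293 at least 2-fold lower. The balance turned without OTC control mice 03 and 67 (1873 higher, 1989 lower) and without these and WT control mouse 13 (1881 and 1923).

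Of 26 tested male-biased liver genes, 23 were lower in OTC and 3 were not called, and 23 were lower when adjusted over the list alone. The list had a median log2 fold change of −2.05 (fry adjusted p = 4.51e-05; adjusted p = 0.679 with an estimated correlation). Hsd3b5, a steroid reductase of male liver, had a median of 1.40 CPM in OTC control and 202 CPM in WT control. The log2 fold change of Hsd3b5 was −5.75 ± 0.89 (adjusted p = 1.46e-06), and −6.38 without OTC control mouse 38. Keg1, a glycine acyltransferase, was lower by −1.70 ± 0.25 log2 (adjusted p = 5.25e-07), and C8b, a subunit of complement, by −1.23 ± 0.22 log2 (adjusted p = 1.49e-05). Among 8 genes with the lowest log2 fold changes, 5 encode major urinary proteins, male-biased carriers of pheromones. Mup10 was at −5.03 ± 0.88, Mup17 at −6.58, Mup9 at −4.84, Mup8 at −4.81 and Mup16 at −4.65. Without OTC control mouse 38, Mup17 was at −7.75, Mup8 at −6.70 and Mup16 at −6.74, without WT control mouse 19, Mup17 was at −5.80, and without OTC control mouse 43, Mup9 was at −6.37. Each of these genes is uncertain because the Mup genes share reads. WT control mouse 13 stood apart from its group, with Hsd3b5 at 1.40 CPM against 81.2 to 270 CPM in the other 9 libraries. The same library had the female-biased genes Cyp2b13 at 154 CPM and Cyp2c40 at 182 CPM, against highest values of 1.66 and 0.849 CPM in the others, although members of these families share reads. The female-biased genes Sult1e1 (0.168 CPM) and Fam107a (0.0561 CPM) were within the range of the others, and the Y-linked gene Ddx3y was at 66.5 CPM against 65.5 to 140 CPM.

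Of 16 genes of the growth hormone and insulin-like growth factor (IGF) axis, 3 were higher, 6 lower and 7 not called, with the same counts adjusted over the list alone. The median was −0.44 (fry adjusted p = 0.00264; adjusted p = 0.679 with an estimated correlation). The growth hormone receptor gene Ghr was lower by −0.96 ± 0.15 log2 (adjusted p = 1.96e-06), and Lifr, a cytokine receptor, by −1.50 ± 0.21 (adjusted p = 2.79e-07). Igfbp1, which encodes a binding protein of IGF, was higher by 3.10 ± 0.61 (adjusted p = 7.08e-05), and by 2.20 without OTC control mouse 03. Female-biased genes were not called as a list, with 8 of 23 higher and 6 lower (fry adjusted p = 0.198).

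Pericentral hepatocytes make glutamine from ammonia, and periportal hepatocytes make urea. Of 22 pericentral genes, 2 were higher, 12 lower and 8 not called, with 2 higher and 13 lower adjusted over the list alone (median −0.61, fry adjusted p = 3.46e-06; adjusted p = 0.596 with an estimated correlation). Glul, which encodes glutamine synthetase, was lower by −1.19 ± 0.24 log2 (adjusted p = 0.000115), from a median of 681 to 324 CPM. Rhbg, an ammonia transporter, was lower by −2.15 ± 0.20 (adjusted p = 2.05e-11), with all 8 OTC control libraries below all 10 WT control libraries. Slc22a3, an organic cation transporter, was lower by −2.51 ± 0.38 (adjusted p = 1.21e-06). Of 21 periportal genes, 11 were higher, 2 lower and 8 not called, with the same counts adjusted over the list alone (median 0.37, fry adjusted p = 0.000795; adjusted p = 0.679 with an estimated correlation). Pck1, a key enzyme of glucose synthesis, was higher by 1.42 ± 0.24 (adjusted p = 6.86e-06), and Asl, the urea cycle enzyme that cleaves argininosuccinate, by 1.26 ± 0.23 (adjusted p = 1.71e-05). Of 16 genes of glutamine and ammonia handling, 3 were higher, 7 lower and 6 not called, with the same counts adjusted over the list alone (median −0.02, fry adjusted p = 0.00475; adjusted p = 0.691 with an estimated correlation). The glutamine transporter genes Slc38a2 and Slc1a5 were among those higher, by 0.79 ± 0.16 and 1.24 ± 0.26. The urea cycle list was not called (4 of 8 genes higher, 1 lower, fry adjusted p = 0.112).

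Of 40 interferon-stimulated genes, 26 were higher, 1 lower and 13 not called, with 27 higher and 1 lower adjusted over the list alone (median 0.50, fry adjusted p = 0.00395; adjusted p = 0.723 with an estimated correlation). Usp18, which restrains interferon signalling, was higher by 2.14 ± 0.23 log2 (adjusted p = 3.85e-10), and Irf7, a transcription factor of the interferon response, by 1.75 ± 0.20 (adjusted p = 3.06e-09). Of 19 p53 targets, 12 were higher, 2 lower and 5 not called, with 14 higher and 2 lower adjusted over the list alone (median 0.60, fry adjusted p = 0.000424; adjusted p = 0.679 with an estimated correlation). Bax, which promotes apoptosis, was higher by 1.02 ± 0.12 (adjusted p = 1.84e-09), and Cdkn1a, an inhibitor of the cell cycle, by 2.21 ± 0.43 (adjusted p = 6.84e-05). Of 16 genes of chaperones and the unfolded protein response of the endoplasmic reticulum, 15 were lower and 1 higher, over all genes and adjusted over the list alone (median −0.72, fry adjusted p = 0.000929; adjusted p = 0.679 with an estimated correlation). Calr, a calcium-binding chaperone, was lower by −0.80 ± 0.12 (adjusted p = 1.38e-06), and Sdf2l1, a cofactor of chaperones, by −1.65 ± 0.35 (adjusted p = 0.000202).

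Of 28 genes of fatty acid oxidation and targets of the lipid sensor PPAR alpha, 3 were higher, 12 lower and 13 not called, with 3 higher and 13 lower adjusted over the list alone. The median was −0.22 (fry adjusted p = 0.0201; adjusted p = 0.769 with an estimated correlation), and the call was lost in a fit of the compared groups only (adjusted p = 0.127) and without WT control mouse 13 and OTC control mice 03 and 67 together (adjusted p = 0.0680). Plin2, which coats lipid droplets, was lower by −1.21 ± 0.21 log2 (adjusted p = 1.08e-05), and Cpt2, a mitochondrial carnitine transferase, by −0.54 ± 0.10 (adjusted p = 1.89e-05). Of 6 erythroid genes, 2 were lower and 4 not called, with 2 lower adjusted over the list alone (median −0.59, fry adjusted p = 0.000219; adjusted p = 0.679 with an estimated correlation). Alas2, which starts heme synthesis in red cells, had a median of 20.6 CPM in OTC and 122 CPM in WT (log2 difference −2.51 ± 0.30, adjusted p = 7.01e-09). Of 12 genes of polyamine metabolism, 3 were higher and 9 not called, with 2 higher adjusted over the list alone (median 0.06, fry adjusted p = 0.000219; adjusted p = 0.723 with an estimated correlation). Azin2, which protects ornithine decarboxylase from degradation, was higher by 1.66 ± 0.31 (adjusted p = 3.92e-05).

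Fmo2, a monooxygenase, was higher by 4.09 ± 0.61 (adjusted p = 7.27e-07), and Usp2, a ubiquitin protease, by 3.42 ± 0.61 (adjusted p = 1.62e-05). The glucocorticoid-responsive gene Fkbp5 was higher by 2.99 ± 0.41 (2.22 without OTC control mouse 03), and Lpin1, a lipid phosphatase, by 2.97 ± 0.45 (2.09 without that library). The serum amyloid genes Saa1 and Saa2, which rise in the acute phase response and share reads, were at −4.91 ± 0.65 and −5.23 ± 0.75, and at −4.21 and −3.83 without WT control mouse 07. On the deposited TPM, the median log2 difference of all genes moved to 0.10 with a pseudocount of 1 and 0.12 with 0.1, and 3882 of 5011 called genes were higher, so the balance of higher and lower genes also depends on the scale. None of the called lists changed the sign of its median under DESeq2 size factors or TPM, in this or any other comparison.

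The comparisons of sh-Gls2 with the control vector ask what lowering Gls2 did in each strain. In both strains most of the tested interferon-stimulated genes, genes of cell division and markers of macrophages rose, as did 11 and 12 of 20 markers of stellate cells. Most targets of NRF2, the transcription factor of the response to oxidants and electrophiles, rose in both. Of enzymes of drug metabolism 11 of 31 rose in each strain, and of genes of the ATF4 stress response 13 of 30 rose in WT and 12 of 30 in OTC. In WT 18 of 24 genes of cholesterol synthesis fell, and in OTC 7 of 8 genes of the urea cycle and 24 of 58 genes of amino acid catabolism fell. No list was called in either strain by camera with an estimated correlation, which compares a list with other genes. For the lists that fry called, the adjusted p of camera was from 0.287 to 0.948 in WT and from 0.467 to 0.929 in OTC. In edgeR, 4638 genes were called in WT, 2344 higher and 2294 lower, and 5690 genes were called in OTC, 2685 higher and 3005 lower. On TPM with a pseudocount of 1 the balance in OTC turned, with 2511 genes higher and 2068 lower, and in WT it turned with no filter (2250 and 2323) and with the filter at 1 CPM (2231 and 2261). In WT 423 genes were at least 2-fold higher and 98 at least 2-fold lower, and in OTC these counts were 473 and 145. No list differed between strains in its response to sh-Gls2 (smallest fry adjusted p = 0.482).

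Pls1, which bundles actin filaments, rose by 5.23 ± 0.41 log2 in WT (adjusted p = 2.64e-15) and by 4.40 ± 0.40 in OTC (adjusted p = 7.1e-13). Slpi, a secreted inhibitor of leukocyte proteases, rose by 3.51 ± 0.33 in WT (adjusted p = 2.04e-12) and by 3.89 ± 0.35 in OTC (adjusted p = 4.46e-13). Gsta1, a glutathione transferase whose family shares reads, rose by 3.37 ± 0.36 in WT and 3.71 ± 0.40 in OTC. Among the 8 highest named genes in WT were also Cib3, a calcium-binding protein, at 5.29 ± 0.44, and Ttc39a at 3.59 ± 0.26. In OTC they included Ly6d, a membrane protein of lymphoid and epithelial cells, at 4.89 ± 0.69, Slc22a7, an organic anion transporter, at 3.94 ± 0.44, and Mki67, a marker of dividing cells, at 3.27 ± 0.40. For each of these genes the ranges of the sh-Gls2 and control libraries did not overlap in the strain named. The lowest values in WT included 5 Mup genes, among them Mup9 at −3.45 ± 1.10 and Mup16 at −1.89 ± 0.65, which are uncertain as members of a family. Mup17 was at −3.50, at −2.72 without WT control mouse 19 and at −4.23 without WT sh-Gls2 mouse 45. Several of the other calls among the lowest values in WT were lost without single libraries. Mup15 (−2.30) lost its call without WT control mouse 77, 19, 07, 10 or 28 and without WT sh-Gls2 mouse 45, 78, 36, 18, 30, 08, 14 or 34, with an adjusted p from 0.0503 to 0.0704. Mt1, a metallothionein, was at −2.01 and at 1.06 without WT control mouse 07 (adjusted p = 0.164), and its call was lost without WT sh-Gls2 mouse 45, 36, 01, 08, 14 or 34 (adjusted p from 0.0555 to 0.0632). Gadd45g, a gene induced by stress, was at −1.80 and at −0.74 without WT control mouse 02 (adjusted p = 0.393), and its call was lost without WT sh-Gls2 mouse 78, 36, 18, 30 or 34 (adjusted p from 0.0509 to 0.0555). Cyp4a14, a fatty acid hydroxylase, was at −1.84, at −1.33 without WT control mouse 13 (adjusted p = 0.081) and at −2.61 without WT sh-Gls2 mouse 79. In OTC the lowest named values included Ces1f, a carboxylesterase, at −1.71 ± 0.39, and Slco1a1, an organic anion transporter, at −2.67 ± 0.80 and at −3.66 without OTC sh-Gls2 mouse 39.

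For several of the lowest named genes in OTC, OTC control mouse 03 decided the value. Ddit4, an inhibitor of growth signalling, was at −1.71 with mouse 03 and at −0.25 without it (adjusted p = 0.738). Setdb2, a histone methyltransferase gene, was at −1.71 and at −0.21 without mouse 03 (adjusted p = 0.554). Phf11c was at −2.46 and at −0.80 without mouse 03 (adjusted p = 0.0859), and Eif4ebp3, an inhibitor of translation, was at −1.87 and at −0.82 without it (adjusted p = 0.15). Pnpla3, a lipase, was at −1.93 and at −1.42 without the unnumbered OTC control library (adjusted p = 0.108).

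Of 40 interferon-stimulated genes, 38 rose in WT and 2 were not called, with 38 adjusted over the list alone (median 1.02, fry adjusted p = 4.09e-07; adjusted p = 0.287 with an estimated correlation). In OTC 30 rose, 1 fell and 9 were not called, with 31 higher and 1 lower adjusted over the list alone (median 0.75, fry adjusted p = 3.95e-05; adjusted p = 0.467 with an estimated correlation). Ifih1, a sensor of double-stranded RNA, rose by 0.86 ± 0.10 log2 in WT (adjusted p = 9.02e-10) and 0.69 ± 0.11 in OTC (adjusted p = 6.45e-07), and Oasl2, a gene of the antiviral response, by 1.60 ± 0.20 and 1.45 ± 0.20. Of 27 cell cycle genes, 21 rose in WT and 6 were not called, with 22 higher and 1 lower adjusted over the list alone (median 1.47, fry adjusted p = 2.59e-06; adjusted p = 0.329 with an estimated correlation). In OTC 21 rose, 2 fell and 4 were not called, with 21 higher and 3 lower adjusted over the list alone (median 1.71, fry adjusted p = 1.88e-05; adjusted p = 0.467 with an estimated correlation). Mki67 rose by 2.38 ± 0.33 in WT, from a median of 2.04 to 7.68 CPM, and Kif20a, a kinesin of cell division, rose by 1.97 ± 0.29 in WT and 2.32 ± 0.34 in OTC.

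Of 18 markers of macrophages and Kupffer cells, 14 rose in WT and 4 were not called, with 15 adjusted over the list alone (median 0.68, fry adjusted p = 8.23e-07; adjusted p = 0.287 with an estimated correlation). In OTC 15 rose and 3 were not called, with 15 adjusted over the list alone (median 0.68, fry adjusted p = 2.16e-06; adjusted p = 0.467 with an estimated correlation). Cd68, a lysosomal protein of macrophages, rose by 1.01 ± 0.12 log2 in WT (adjusted p = 3.67e-09) and 1.15 ± 0.13 in OTC (adjusted p = 5.12e-10), and Cd14, a receptor for bacterial lipopolysaccharide, by 1.85 ± 0.27 and 1.85 ± 0.29. Of 20 markers of stellate cells and fibrosis, 11 rose in WT and 9 were not called, with 14 adjusted over the list alone (median 0.46, fry adjusted p = 0.00172; adjusted p = 0.729 with an estimated correlation). In OTC 12 rose and 8 were not called, with 13 adjusted over the list alone (median 0.51, fry adjusted p = 3.95e-05; adjusted p = 0.467 with an estimated correlation). Reln, a secreted glycoprotein of stellate cells, rose by 0.53 ± 0.11 in WT and 0.67 ± 0.12 in OTC. Of 14 sinusoidal endothelial markers, 10 rose in OTC and 4 were not called, with 11 adjusted over the list alone (median 0.31, fry adjusted p = 0.000542; adjusted p = 0.586 with an estimated correlation). Eng, a receptor of endothelial cells, rose by 0.42 ± 0.09 in OTC (adjusted p = 7.02e-05).

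Of 18 NRF2 targets, 12 rose in WT and 6 were not called, with 12 adjusted over the list alone (median 0.51, fry adjusted p = 4.09e-07; adjusted p = 0.287 with an estimated correlation). In OTC 12 rose and 6 were not called, with 13 adjusted over the list alone (median 0.38, fry adjusted p = 2.66e-06; adjusted p = 0.467 with an estimated correlation). Gsr, which keeps glutathione reduced, rose by 0.81 ± 0.08 log2 in WT (adjusted p = 1.37e-12) and 0.82 ± 0.08 in OTC (adjusted p = 1.09e-11). Abcc4, an exporter of bile acids and drug conjugates, rose by 1.84 ± 0.34 in WT and 2.78 ± 0.36 in OTC. Of 31 genes of xenobiotic metabolism, 11 rose in WT and 20 were not called, with 12 adjusted over the list alone (median 0.37, fry adjusted p = 1.77e-05; adjusted p = 0.447 with an estimated correlation). In OTC 11 rose, 2 fell and 18 were not called, with 12 higher and 2 lower adjusted over the list alone (median 0.28, fry adjusted p = 4.25e-05; adjusted p = 0.467 with an estimated correlation). The family members Gstm3 and Gsta2, glutathione transferases with uncertain single-gene values, rose by 2.12 ± 0.32 and 1.68 ± 0.23 in WT. Of 30 genes of ATF4 and the amino acid response, 13 rose, 3 fell and 14 were not called in WT, with the same counts adjusted over the list alone (median 0.20, fry adjusted p = 1.08e-07; adjusted p = 0.287 with an estimated correlation). In OTC 12 rose, 4 fell and 14 were not called, with the same counts adjusted over the list alone (median 0.19, fry adjusted p = 2.33e-05; adjusted p = 0.467 with an estimated correlation). Atf3, a stress-induced transcription factor, rose by 2.15 ± 0.21 in WT and 1.70 ± 0.21 in OTC. In OTC Slc7a11, the cystine importer, rose by 3.54 ± 0.50 and Aldh1l2, a mitochondrial folate enzyme, fell by 2.00 log2 with an SE of 0.33.

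Of 8 urea cycle genes, 7 fell in OTC and 1 was not called, with 7 adjusted over the list alone (median −0.44, fry adjusted p = 0.00032; adjusted p = 0.573 with an estimated correlation). Cps1, which makes carbamoyl phosphate from ammonia, was at −0.53 ± 0.12 log2 (adjusted p = 0.000493), and Arg1, the arginase of liver, at −0.70 ± 0.15 (adjusted p = 0.000189). In WT 1 of the 8 genes was lower and the list was not called (fry adjusted p = 0.0679). Of 58 genes of amino acid catabolism, 5 rose, 24 fell and 29 were not called in OTC, with 6 higher and 25 lower adjusted over the list alone (median −0.18, fry adjusted p = 0.0127; adjusted p = 0.929 with an estimated correlation). The call of this list was lost in a fit of the compared groups only (adjusted p = 0.0529) and without OTC control mice 03 and 67 (adjusted p = 0.265). Cbs, which makes cystathionine from homocysteine, was at −0.63 ± 0.08 (adjusted p = 2.17e-09), with all OTC sh-Gls2 libraries below all OTC controls. Of 24 genes of cholesterol synthesis, 18 fell in WT and 6 were not called, with 21 adjusted over the list alone (median −0.61, fry adjusted p = 0.00237; adjusted p = 0.729 with an estimated correlation). Idi1, an isomerase of the pathway, was at −0.97 ± 0.21 (adjusted p = 0.000338), and Srebf2, the transcription factor that drives the pathway, at −0.41 ± 0.07 (adjusted p = 1.89e-05).

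Of 22 pericentral genes, 4 rose, 2 fell and 16 were not called in WT, with the same counts adjusted over the list alone (median 0.20, fry adjusted p = 0.0175; adjusted p = 0.948 with an estimated correlation). In OTC 10 rose, 2 fell and 10 were not called, with the same counts adjusted over the list alone (median 0.35, fry adjusted p = 2.14e-05; adjusted p = 0.467 with an estimated correlation). Rhbg rose by 1.18 ± 0.16 log2 in WT and 2.34 ± 0.20 in OTC, and Lect2, a protein secreted by pericentral hepatocytes, rose by 0.74 ± 0.16 and 1.15 ± 0.17. Of 12 polyamine genes, 1 rose and 2 fell in WT and 9 were not called, with the same counts adjusted over the list alone (median −0.15, fry adjusted p = 0.0028; adjusted p = 0.889 with an estimated correlation). In OTC 2 rose, 3 fell and 7 were not called, with the same counts adjusted over the list alone (median −0.14, fry adjusted p = 3.04e-06; adjusted p = 0.486 with an estimated correlation). Oaz1, the antizyme that directs ornithine decarboxylase to the proteasome, was at −0.51 ± 0.06 in WT (adjusted p = 2.05e-10) and −0.76 ± 0.06 in OTC (adjusted p = 7.28e-15). Of 16 genes of the growth hormone and IGF axis, 1 rose, 5 fell and 10 were not called in WT, with the same counts adjusted over the list alone (median −0.29, fry adjusted p = 0.00425; adjusted p = 0.729 with an estimated correlation). In OTC 2 fell and 14 were not called, with 2 adjusted over the list alone (median −0.23, fry adjusted p = 0.0105; adjusted p = 0.922 with an estimated correlation), and the call was lost without OTC control mice 03 and 67 (adjusted p = 0.0722). Igfals, which stabilises IGF in blood, was at −0.50 ± 0.12 in WT and −0.61 ± 0.13 in OTC. Of 19 p53 targets, 9 rose, 2 fell and 8 were not called in WT, with 12 higher and 2 lower adjusted over the list alone (median 0.37, fry adjusted p = 0.0176; adjusted p = 0.948 with an estimated correlation). Btg2, an inhibitor of proliferation, rose by 0.84 ± 0.21 in WT (adjusted p = 0.00128). Of 23 female-biased genes, 8 rose, 1 fell and 14 were not called in OTC, with the same counts adjusted over the list alone (median 0.53, fry adjusted p = 0.0469; adjusted p = 0.929 with an estimated correlation). Prom1, a membrane protein also of bile duct progenitors, rose by 3.27 ± 0.42 in OTC (adjusted p = 9.94e-09).

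**Figure D2:**
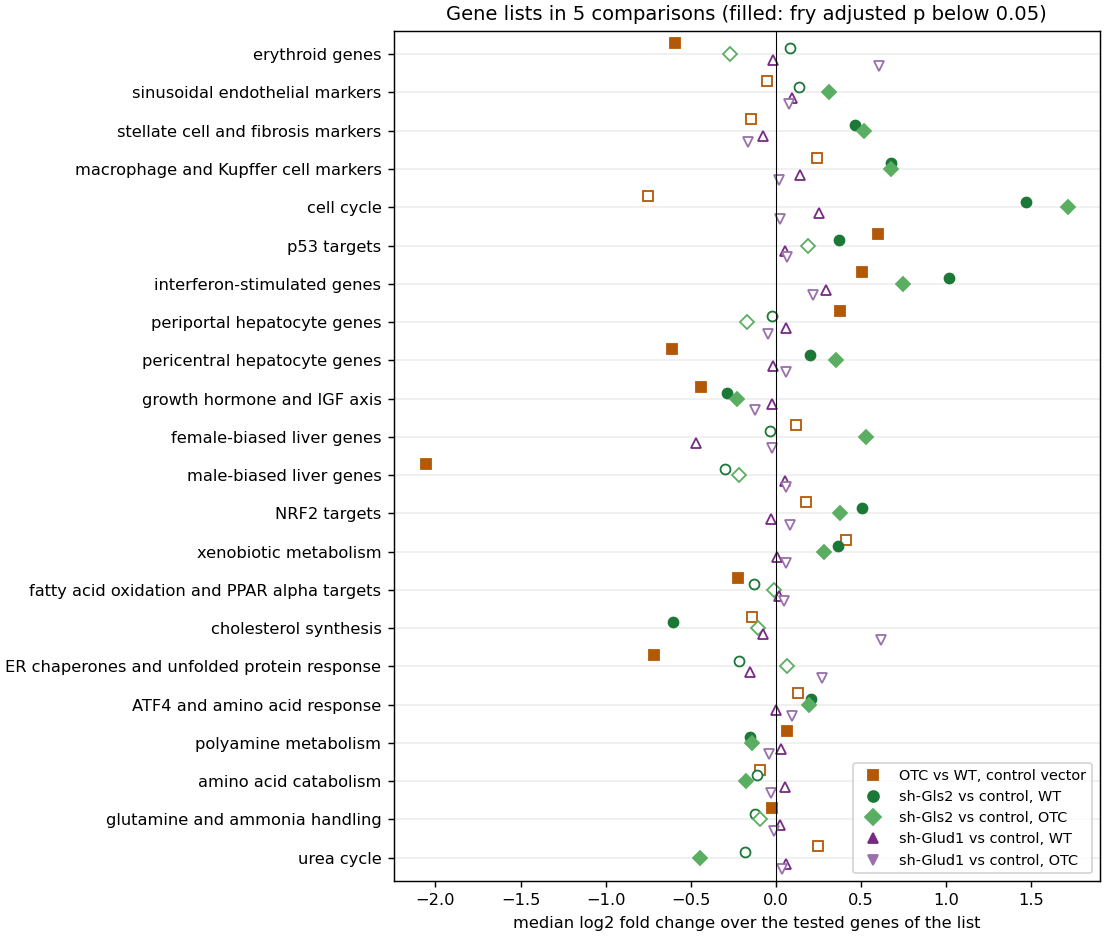
Median log2 fold change over the tested genes of 22 gene lists in 5 comparisons, with filled markers where the fry adjusted p is below 0.05. The male-biased list was at −2.05 in OTC against WT, the cell cycle list was at 1.47 and 1.71 under sh-Gls2 in WT and OTC, and no marker of sh-Glud1 is filled.

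Across all 13311 tested genes the log2 fold changes of sh-Gls2 in WT and OTC had a Pearson correlation of 0.78 and a Spearman correlation of 0.77; genes are not independent replicates. Of genes higher in WT and in OTC, 1750 were shared, where 473 would be shared if the calls were independent. Of genes lower, 1661 were shared, where 518 would be shared if the calls were independent. Pls1 and Slpi were among the shared genes, and 5 genes were called in opposite directions.

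**Figure D3:**
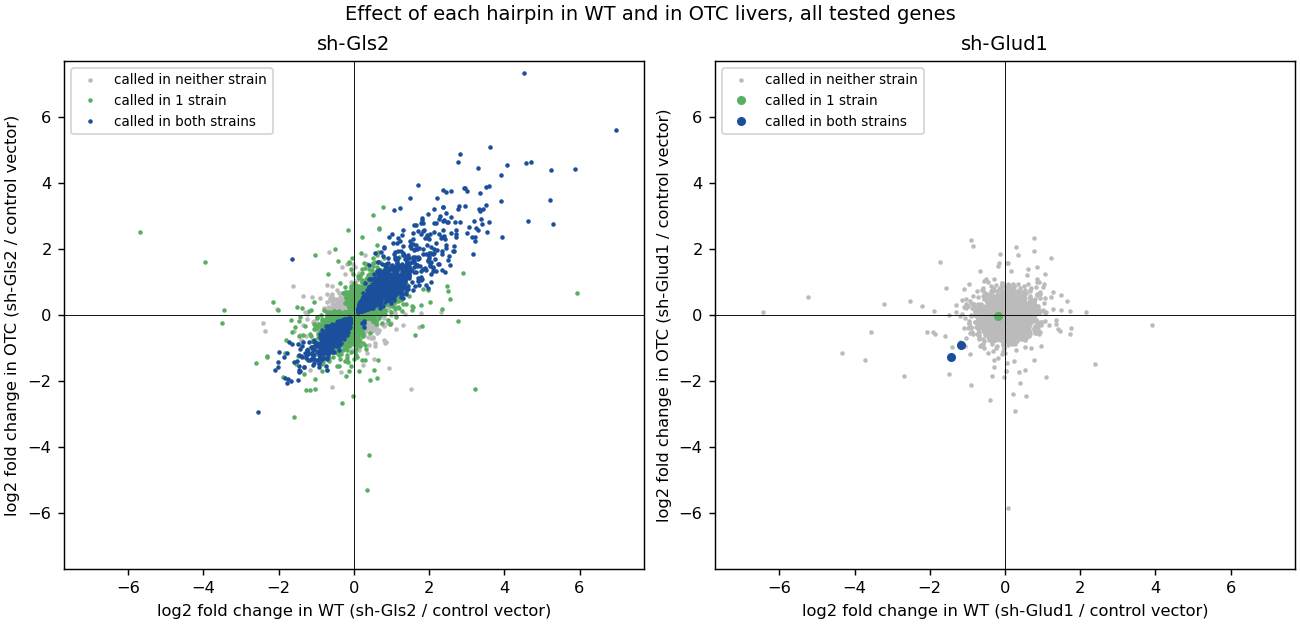
Log2 fold change of each tested gene in WT (horizontal axis) and in OTC (vertical axis), for sh-Gls2 on the left and sh-Glud1 on the right, coloured by calls in neither, 1 or both strains. Under sh-Gls2, 3411 genes were called in the same direction in both strains; under sh-Glud1, 2 genes were.

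The comparisons of sh-Glud1 with the control vector ask what lowering Glud1 did in each strain. Glud1 itself fell, and few other genes were called. In edgeR, 3 genes were lower and none higher in WT, with 697 at an unadjusted p below 0.05, and DESeq2 called 4. In OTC 2 genes were lower and none higher in edgeR, with 639 at an unadjusted p below 0.05, and DESeq2 called 3. Gm3219, a processed pseudogene directly downstream of Glud1 on the same strand (chromosome 14, 34345281 to 34345583), was called in WT (−1.18 ± 0.16 log2, adjusted p = 3.82e-06) and in OTC (−0.92 ± 0.17, adjusted p = 0.00735). Its reads are uncertain because of its position next to Glud1. It was outside the naming rule and was named after its values were seen. Zdhhc6, a palmitoyltransferase (chromosome 19, 55271291 to 55316032), was called in WT at −0.20 ± 0.04 (adjusted p = 0.0328). The call of Zdhhc6 was lost without WT control mouse 02, 07, 10, 19, 28 or 41 and without WT sh-Glud1 mouse 15, 17, 32, 56, 57, 69 or 70, with an adjusted p from 0.0532 to 0.186. Without OTC sh-Glud1 mouse 58 or 65, 3 genes were called in OTC.

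No list was called by fry under sh-Glud1 in WT (smallest adjusted p = 0.356) or in OTC. Cholesterol synthesis came nearest in OTC, with a median of 0.61 over 24 genes (fry adjusted p = 0.0601; adjusted p = 0.0363 with an estimated correlation). Of these 24 genes, 18 were higher adjusted over the list alone, and none was called over all genes. The 8 urea cycle genes held no call under sh-Glud1 in either strain.

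The difference between strains in the effect of sh-Gls2 was called for 45 genes in edgeR, 16 with a higher and 29 with a lower effect in OTC. Ces2c, a carboxylesterase, rose by 1.08 ± 0.24 log2 in WT and 3.17 ± 0.28 in OTC, a difference of 2.09 ± 0.36 (adjusted p = 0.00374). Slc13a3, a dicarboxylate transporter of pericentral hepatocytes, rose by 0.94 ± 0.18 in WT and 2.38 ± 0.21 in OTC (difference 1.44 ± 0.27, adjusted p = 0.00508). Pfn2, an actin-binding profilin, rose by 3.17 ± 0.17 in WT and 1.85 ± 0.17 in OTC (difference −1.32 ± 0.23, adjusted p = 0.00379). Nlrp6, a sensor of the innate immune system, was at −0.70 ± 0.08 in WT and −1.34 ± 0.09 in OTC (difference −0.63 ± 0.12, adjusted p = 0.00508). Rpl3, a ribosomal protein gene, was not called in WT (−0.18) and fell in OTC (−0.84), a difference of −0.66 ± 0.12 (adjusted p = 0.00505). The difference for Rhbg was 1.17 ± 0.26 (adjusted p = 0.0249), and its call was lost without OTC control mouse 35 (adjusted p = 0.0524) or 03 (adjusted p = 0.0566). The count of 45 was 15 without OTC control mouse 35, 17 without OTC control mouse 03, 26 without WT sh-Gls2 mouse 14 or OTC sh-Gls2 mouse 74, 27 without OTC sh-Gls2 mouse 49, 28 without OTC sh-Gls2 mouse 31 and 29 without WT control mouse 19. The difference between strains in the effect of sh-Glud1 was called for 0 genes in edgeR, with 417 at an unadjusted p below 0.05, and DESeq2 and limma on TPM also called 0.

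The comparison of sh-Gls2 with sh-Glud1 within a strain sets livers with different active hairpins beside each other. In edgeR 5395 genes were called in OTC, 2593 higher and 2802 lower under sh-Gls2, and 3946 in WT, 2062 higher and 1884 lower. In OTC the balance turned in DESeq2 (2724 higher, 2705 lower) and in a fit of the compared groups only (2531 and 2488), and it widened on TPM with a pseudocount of 1 (1881 and 2640). Subunits of the proteasome, the protein-degrading complex, were among the genes with the smallest adjusted p. Psmc6, an ATPase of the complex, was higher by 0.70 ± 0.05 log2 in OTC (adjusted p = 1.24e-17) and 0.80 ± 0.04 in WT (adjusted p = 1.43e-20), and Psmb7, a catalytic subunit, by 0.59 ± 0.04 and 0.67 ± 0.04. Shfm1, which also serves as a subunit of the proteasome, was lower by −1.37 ± 0.08 in OTC and −1.24 ± 0.07 in WT. Slc20a2, a phosphate transporter, was lower by −1.33 ± 0.07 in OTC (adjusted p = 1.06e-21) and −1.38 ± 0.07 in WT (adjusted p = 7.72e-23), and Gnai3, a subunit of G proteins, by −0.85 ± 0.06 and −0.83 ± 0.05. For these 5 genes the ranges of the 2 groups did not overlap in either strain.

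By fry 17 lists were called in OTC and 17 in WT between the hairpins; none was called with an estimated correlation (adjusted p from 0.606 to 0.795 in OTC and from 0.503 to 0.795 in WT). In a fit of the compared groups only, the fry calls of pyrimidine metabolism (adjusted p = 0.0520) and of ATF4 and the amino acid response (adjusted p = 0.127) were lost in OTC, and with the mouse number as a covariate that of the p53 targets was lost in WT (adjusted p = 0.0639). Of 8 urea cycle genes, 7 were lower under sh-Gls2 in OTC and 1 was not called, with 7 adjusted over the list alone (median −0.46, fry adjusted p = 0.000107). In WT 3 were lower and 5 not called, with 3 adjusted over the list alone (median −0.24, fry adjusted p = 0.015). Of 24 genes of cholesterol synthesis, 21 were lower in OTC and 3 not called, with 22 adjusted over the list alone (median −0.72). In WT 14 were lower, with 18 adjusted over the list alone (median −0.50). In OTC the mean log2 CPM of this list was 6.82 ± 0.23 under sh-Gls2 (SD, n = 10) and 6.81 ± 0.64 under control (SD, n = 8). It was 7.44 ± 0.47 under sh-Glud1 (SD, n = 8), so in OTC the list was not lower under sh-Gls2 than under control. Of 13 mitochondrially encoded genes, 8 were higher in OTC and 5 not called, with 9 adjusted over the list alone (median 0.38). The polyamine list in WT was the only called list whose median (−0.06), mean (0.06) and fry direction (lower) differed in sign.

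The study's question of relief can be put as whether a hairpin moved genes against their difference between OTC and WT. Of the 4830 genes that differed between OTC and WT, 61.7% moved the opposite way under sh-Gls2 in OTC and 63.3% under sh-Glud1. Both comparisons share the OTC control libraries, which alone gives a share above 50%. In 20 simulations with no effect of the hairpin, the share was 61.4% on average for sh-Gls2 (60.8% to 62.6%) and 60.8% for sh-Glud1 (59.5% to 63.2%). The covariance of the fold changes was −0.10 for sh-Gls2 against −0.06 in the simulations (SD 0.01), and −0.08 for sh-Glud1 against −0.06 (SD 0.02). Their correlation was −0.21 for sh-Gls2 against −0.29 in the simulations, and −0.42 for sh-Glud1 against −0.27. The simulations drew each gene independently, so their ranges and SD are a lower limit of the spread between real libraries. With the OTC controls split so that no library served in both comparisons, the share over 20 splits was 57.6% on average for sh-Gls2 (46.6% to 65.9%) and 52.2% for sh-Glud1 (27.6% to 71.003%). Over the same splits the covariance was −0.044 on average for sh-Gls2 (−0.20 to 0.15) and −0.028 for sh-Glud1 (−0.18 to 0.17). The shares fell on both sides of 50% and the covariances took both signs, so a reversal was not shown for either hairpin. Rhbg and Slc13a3 were lower in OTC than in WT and rose under sh-Gls2 in OTC, but they also rose in WT, by 1.18 and 0.94 log2. Irf7 was higher in OTC than in WT and rose further under sh-Gls2 (1.01 log2, edgeR adjusted p = 6.1e-05).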

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

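Chosen only after the result was seen were the tests of depth and RNA composition, hepatocyte share, the 2 outlying OTC control libraries, time of day, and weak repression through 1 site in 3′ UTRs and in coding sequences. In each group of 8 to 10 libraries, the highest and lowest library were compared with the rest on a set of measures, 90 tests in all. A library stood apart by Dixon's test in 4 of them. Chance flags about 1 in 20 such groups (5%), so 4 of 90 is no more than chance would give. This rate covers all tests together, so it does not decide whether any single library differs from its group.

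In WT control, mouse 13 had a male-biased score (mean log2 CPM of the list) of 5.59 against 7.11 to 8.62 in the others, a gap of 0.503 of the group's range. In WT sh-Glud1, mouse 56 had a cell cycle score of 1.41 against 0.35 to 0.89 in the others, a gap of 0.496 of the range. In OTC sh-Glud1, mouse 42 had Otc at 6.22 log2 CPM against 5.69 to 5.88 in the others, a gap of 0.645 of the range. In OTC sh-Glud1, mouse 58 had an interferon score of 2.59 against 3.61 to 4.28 in the others, a gap of 0.605 of the range.

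The effect of sh-Gls2 differed between strains for 45 genes in edgeR, by a test of the difference itself. The named differences, OTC minus WT on the log2 scale, were 2.09 for Ces2c, 1.44 for Slc13a3, 0.66 for Cyp2a12, 1.11 for E2f1, 1.17 for Rhbg, −1.32 for Pfn2, −0.66 for Rpl3, −0.63 for Nlrp6, −0.47 for Gpi1 and −0.57 for Zcchc7. The call for Rhbg was lost without OTC control mouse 35 (adjusted p = 0.0524) or 03 (adjusted p = 0.0566). Cyp2a12 belongs to a family that shares reads.

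The response to sh-Gls2 covered 4638 genes in WT and 5690 in OTC, while sh-Glud1 lowered its target to 37.3% and 41.6% of control with few other calls. Repression of many transcripts by a guide from the hairpin was tested on all 7-base sites in 3′ UTRs. The lowest site that Gls2 also holds had t = −5.57 in the strain where it was weaker, short of the bound of t = −8 set beforehand. The test averages over all genes with a site, so it cannot exclude strong repression of a few transcripts. Shfm1 was at −1.17 in WT and −1.36 in OTC, with Gls2 at −1.11 and −1.15, and the cause was not tested. Displacement of the liver microRNA miR-122 was argued against by t = −1.62 for its sites. The mitochondrial share was higher under sh-Gls2 (12.3 ± 0.500% against 11.4 ± 0.637% in WT, SD, n = 10 and 10; 13.1 ± 0.883% against 11.4 ± 1.51% in OTC, SD, n = 10 and 8), but with total counts, the Rn45s share and the mitochondrial share as covariates, the last of which had 2960 genes called for it, 88.1% of the reported calls in WT and 83.6% in OTC stayed in the same direction, which argues against depth or RNA composition as the whole cause. Weak repression may contribute, since the site TGCTTCA ranked 1 of 15731 from the lowest in WT (t = −5.96) and in OTC (t = −5.57). Under sh-Glud1 the same site had t = 0.609 in WT and −1.17 in OTC. Gls2 holds it on chromosome 10 in the coding sequence (128209347 to 128209353) and in the 3′ UTR (128209467 to 128209473). Of all tested sites, 14.7% occur in Gls2, as do 4 of the 10 lowest, some of which overlap. In a regression, the 1869 genes with TGCTTCA in the 3′ UTR had log2 fold changes lower by 0.08 on average in each strain. For TGCTTCAA, which Gls2 holds once, in its coding sequence, the value was 0.11 over 407 genes. The overlapping GCTTCAA had t = −5.32 and −5.27 over 1071 genes. TGCTTCA held 0.289% and 0.252% of the variance and had no such association in coding sequences (t = 0.487). The regression does not show that the site itself lowered these genes. The loss of Gls2 itself stays open as the biological explanation, untested, because the knockdown and any other effect of this hairpin are in the same libraries.

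Markers of macrophages, stellate cells, dividing cells and, in OTC, endothelial cells rose together under sh-Gls2. A lower share of hepatocyte RNA would raise the markers of every other cell type alike. On the log2 scale, the gap between the highest and the lowest of 6 cell type lists was 0.65 (SE 0.15) in WT. In OTC it was 0.51 (SE 0.17), and macrophage markers were highest in both strains. The highest and lowest lists were picked by these same values. The SE leaves out that choice, so the gap alone does not decide the question. Macrophage markers were at 0.68 (SE 0.09) in WT and 0.78 (SE 0.12) in OTC by group means of log2 CPM, while B and plasma cell markers were at 0.02 in WT and cholangiocyte markers at 0.27 in OTC. Endothelial markers were at 0.15 (SE 0.07) in WT and 0.32 (SE 0.08) in OTC. None of these lists shares a tested gene with another list, and C1qb of the macrophage list had a median of 23.7 CPM in WT sh-Gls2 and 14.4 CPM in WT control. The unequal rise of macrophage and endothelial markers argues against a smaller share of hepatocytes as the whole cause, for these markers only. A smaller share may still contribute, since the medians of all 6 lists were above 0 in both strains. A gain in macrophages, or a change of expression within them, may remain and was not tested.

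Male-biased genes were lower in OTC controls, and OTC control mice 03 and 67 stood apart from their group on the third principal component (−40.9 and −29.9 against 12.6 to 24.2), which held 4.71% of the variance, as OTC sh-Glud1 mice 65 and 58 did from theirs (−27.8 and −15.9 against 12.5 to 23.7). Without both, the median of the list was −1.80, and 19 of 26 genes were still called lower, which argues against these libraries as the cause. A shift in the time of day of collection could not be told apart from the strain: a contrast of clock genes differed by −1.14 SD of the WT controls, with overlapping ranges of −2.52 to 3.90 in WT and −4.48 to 0.68 in OTC. The variant in Otc and the strain background may each contribute, and the design confounds them.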

How the results depend on the processing

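Chosen after seeing the data were the fits without WT control mouse 13, without OTC control mice 03 and 67, and without these 3 libraries, and the omission of single libraries for each named gene. For named genes, 2025 of 2112 values under an alternative kept their direction and their side of the threshold, 67 kept the direction and lost the call, and 20 reversed. For lists, 384 of 485 kept both and 101 lost the call. Of these, 71 were lost in camera with an estimated correlation. With camera's preset correlation 22 were lost, and 49 of 71 lists kept the call. No list changed direction. For the changes below the cause was not tested unless the setting itself shows it.

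Counts of calls within 1.5 times the reported one are not repeated. In OTC, sh-Glud1 gave 1 gene in a fit of the compared groups only and with the mouse number as a covariate. The strain difference in the sh-Gls2 effect gave 24 genes with no filter, 76 in DESeq2, 19 in a fit of the compared groups only, 21 and 23 on TPM with pseudocounts of 1 and 0.1, 10 without OTC control mice 03 and 67 and 12 without the 3 libraries, the last 2 with fewer samples. The count of lists called with an estimated correlation was 0 in the comparisons of OTC with WT, of sh-Gls2 with control in WT and in OTC, and of both hairpins in OTC and in WT, and 1 for sh-Glud1 in OTC, where the mouse number also gave 1. With camera's preset correlation it was 9 for sh-Glud1 in WT, 10 in OTC, and 6 and 9 for the strain differences in sh-Gls2 and sh-Glud1. Over all tested genes in place of those called, 55.9% moved against the strain difference under sh-Gls2 (56.6% in simulations with no effect, 55.9% to 57.2%) and 58.2% under sh-Glud1 (56.1% in simulations, 55.3% to 56.9%). With the OTC controls split, these shares were 52.7% on average (47.8% to 55.5%) under sh-Gls2 and 50.9% (37.9% to 60.2%) under sh-Glud1.

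Reversed on both TPM scales were Gls2 in OTC against WT (0.10), Otc under sh-Gls2 in WT (0.048), Glud1 under sh-Gls2 in OTC (0.036), Gls2 under sh-Glud1 in OTC (0.045), Otc under sh-Glud1 in OTC (0.055 and 0.056), Mt1 under sh-Gls2 in WT (0.31 and 0.35) and Ddit4 under sh-Gls2 in OTC (0.084 and 0.17). Mt1 was at 0.94 in DESeq2. With the mouse number as a covariate, Glud1 was at 0.020 under sh-Gls2 in OTC. Without OTC control mice 03 and 67, under sh-Gls2 in OTC, Glud1 was at 0.0061, Eif4ebp3 at 0.49, Setdb2 at 0.080 and Ddit4 at 1.40 (adjusted p = 0.017). Reversals without a call in either setting are changes of sign near 0.

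With each library left out in turn, counts ranged from 4001 to 4940 for OTC against WT, 4258 to 4818 and 5334 to 5680 for sh-Gls2 in WT and OTC, 2 to 3 for sh-Glud1 in WT and in OTC, 15 to 64 for the strain difference in sh-Gls2, and 5030 to 5456 and 3641 to 4027 between hairpins in OTC and WT. Reversed values ranged from −0.072 to 0.037 for Gls2 in OTC against WT, −0.066 to 0.037 for Gls2 under sh-Glud1 in OTC, −0.085 to 0.025 for Gls2 under sh-Glud1 in WT, −0.047 to 0.019 for Glud1 under sh-Gls2 in OTC, −0.022 to 0.017 for Otc under sh-Gls2 in WT and −2.35 to 1.06 for Mt1 under sh-Gls2 in WT, whose highest was without WT control mouse 07. On TPM, 77.5% of called genes were higher in OTC against WT, where counts gave 54.9%. The depth of 14489866 to 22781052 counts limits genes of few counts, of which the filter removed those outside the 13311 tested.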

Other observations

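The list of proteasome subunits was written only after Psmc6, Psmb7 and Psmd14 were seen, so its test was chosen after the result was seen, as were the permutation of residuals and the look at which libraries the highest random splits kept together. It holds 33 constitutive subunits, all tested. Under sh-Gls2 in WT, 30 were higher, 2 lower and 1 not called, with 32 adjusted over the list alone (median 0.61, fry p = 2.29e-21; p = 8.09e-06 with an estimated correlation). In OTC 30 were higher, 2 lower and 1 not called, with 32 adjusted over the list alone (median 0.48, fry p = 2.94e-17; p = 0.000694 with an estimated correlation). Shfm1 (−1.17 in WT and −1.36 in OTC) and Psmd3 (−0.36 and −0.56) were the lower subunits, and Adrm1, a ubiquitin receptor of the complex, was not called in either strain. Psmc6, an ATPase of the complex, rose by 0.81 in WT and 0.74 in OTC, and Psmb4, a subunit of the core, by 0.85 and 0.68. Under sh-Glud1, edgeR called none of the 33 in WT (fry p = 0.409) or in OTC (fry p = 0.103).

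The libraries of each comparison were also split at random into groups of the same sizes, with fits of the compared groups only. In OTC against WT the real split called 3691 genes and the highest other split 2, so 1 of 100 splits, the real one, gave as many, and chance can be excluded. It can also be excluded for sh-Gls2 in WT (4884 real, 1 in the highest other split), for sh-Gls2 in OTC (5144 and 3152), for sh-Gls2 against sh-Glud1 in OTC (5019 and 1) and in WT (4803 and 56), each with 1 of 100 splits as large. For sh-Glud1 in WT the real split called 3 genes and another called 175, with 4 of 100 as large. In OTC the real split called 1 and another 4, with 2 of 100 as large. Both shares were under the 5% set beforehand, which met that rule. At least 1 gene was called in 8 other splits in WT and in 1 other split in OTC. The genes called under sh-Glud1 in the fit of all libraries include Glud1 itself, whose knockdown alone can give a call. The splits therefore do not exclude chance for any other gene, and do not show that any other gene changed. For the strain difference in the sh-Gls2 effect the real split called 19 and another 1562, with 2 of 60 as large, and for that in the sh-Glud1 effect the real split called 0 and another 540, with all 60 as large. Splits of strain within a vector also break the strain effect itself, so they decide nothing about these differences. With the strain and vector effects kept and the residuals of log2 CPM permuted, limma called 24 genes for the sh-Gls2 difference against 9 in the highest of the others, with 1 of 100 as large. By this test chance can be excluded for the count of 24 where no library is left out, and the 45 genes of edgeR were not tested so. Permuted residuals take the groups as equally spread, but the mitochondrial share had an SD of 1.51% in OTC control and 0.637% in WT control. For the sh-Glud1 difference limma called 0 against 58, with 100 of 100 as large, which a count of 0 fixes. The split with 3152 calls kept 16 of 18 libraries together as in the real groups, with the labels swapped, where the median of the other splits was 10. The split with 1562 calls kept 18 of 20 sh-Gls2 libraries by strain (median 12) but 12 of 18 controls (median 10), so the strain difference stayed more in one vector than in the other. The split with 540 calls was uneven by strain as well, with 14 of 18 controls kept (median 10) and 11 of 17 sh-Glud1 libraries (median 10). The split with 175 calls kept 13 of 19 libraries (median 11). Splits that call many times the real count point to a structure of the samples; for 540 and 1562 the strain may be that structure, and its source was tested for none of them.

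With the mouse number as a covariate, 486 of 13359 genes were called for the number itself over 54 libraries. The sum of the mitochondrially encoded counts was 11.4 ± 1.51% of the total in OTC control (SD, n = 8), 13.1 ± 0.883% in OTC sh-Gls2 (SD, n = 10) and 10.4 ± 1.03% in OTC sh-Glud1 (SD, n = 8).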
